A study of Saccharomyces cerevisiae with 29 samples.

How the data were processed

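Native MNase-seq was done on budding yeast grown in complete synthetic medium to log phase; nuclei were purified from spheroplasts and treated with MNase, and libraries were made with a commercial DNA kit, per the labels' protocols. Bowtie2 is named in the submitters' processing notes, without a version. The genome build, the filters on fragment length and the handling of duplicates are not given in the sources used here. Each library came as whole-number counts of fragment midpoints per position, and these deposited counts carry no normalization. Fragment lengths are not part of the values used here, so nucleosomes and shorter protected fragments cannot be told apart. In 28 of the 29 libraries 1 line had a count without a chromosome; it held 1.39 to 9.61% of the counts and was left out, as was the mitochondrial genome (at most 0.0432% of midpoints).

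Groups follow the labelled distance between Rap1 and Abf1. The deletion strains had 1 library each and the strain without a deletion 2; nothing says whether these came from separate cultures. Counts of these 2 libraries in 1 kb windows gave a chi-square per degree of freedom of 8.68, and all 406 pairs of libraries 2.15 to 67.8. PCR copies and library preparation alone raise this value, so it does not decide whether any library repeats another; libraries were counted as labelled.

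No reference sequence was used, so motif positions are not analysed here. For that case, the rule fixed before the data were examined places the sites at the centres of depleted regions of the no-deletion libraries. These are regions below 0.25 of the genome mean after smoothing. The Rap1 point, the centre of the promoter region, follows this rule. The Abf1 point does not. It lies at the labelled distance from the Rap1 point, the placement planned for strain-specific coordinates, and 127.5 bp from the centre of the nearest depleted region. The centre of a depleted region is itself an approximation to a site. Moving the points, also to that nearest centre for Abf1, was tried as an alternative. Coordinates on chromosome 3 are specific to each strain, as the shift that best aligned each library with a no-deletion library right of HML showed. Gene names and starts come from the R64 gene table; the deposited coordinates name no build, so none of its coordinates are printed. Starts on the other 15 chromosomes had the depleted region upstream of them in the deposited coordinates; chromosome 3 was left out of the gene average because its genes were offset.

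Counts were divided by the genome mean per bp of the same library. Density was smoothed with a Gaussian of SD 20 bp, and summits at least 0.5 of the genome mean and at least 100 bp apart were called dyads. In simulated intervals with dyads of height 1 and 3, 99.5 to 100% were recovered within 20 bp at the lowest, median and highest depth. The simulation had no dyads between the minimum height of 0.5 and 1, and no PCR copies. It therefore does not cover weaker calls, which include most of those near 133 and 435 bp from Rap1. Relations with distance used Spearman and Pearson correlations with 100000 permutations over strains. In 500 simulations without a relation, with 1000 resamples each, 4.6% of tests had p under 0.05. Classes were compared with exact permutation tests, and adjusted values are Benjamini-Hochberg values.

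Genome windows of 1 kb, with the interval between the sites left out, were tested on the deposited counts against distance with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, filterByExpr), with DESeq2 1.42.0 as an alternative, in R 4.3.3. Of 12055 windows, 12032 passed the filter, and the biological coefficient of variation was 7.27%. The simulation used the common dispersion of 0.00529; 100 windows had each slope, and 10 unchanged windows were called. The windows to be named were the 20 with the smallest adjusted p among those under 0.05, of which there were 0. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

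Alternatives covered smoothing, the height and separation of summits, normalization to 20 kb beyond HML, a limit on midpoints per position, trimmed intervals, other class limits and periods, added or removed libraries, and partial correlations. Added after the data were seen were moved reference points, the left-out or corrected libraries whose coordinates differ from the label, a partial correlation given the depletion before genes, intervals counted from the edge of the promoter depleted region, strains of 300 bp and more, and each library left out in turn for the relations at HML. Intervals cover counting error only, since PCR copies are not independent molecules.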

Results

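Nucleosome positions were measured by native MNase-seq in strains of budding yeast that carry the silent mating-type locus HMLα with the α2 gene replaced by CRE, which encodes a site-specific recombinase. MNase digests the DNA between nucleosomes, so the midpoint of a protected fragment marks the centre, or dyad, of a nucleosome. The series varied the distance between the Rap1 site of the promoter and the Abf1 site further along the locus. Rap1 and Abf1 are DNA-binding factors that keep nucleosomes off their sites. The labelled distance is that between the sites, and the centres of the depleted regions found nearest to them in the strain without a deletion lay 1587.5 bp apart. There were 29 libraries from 28 strains. The strain without a deletion, with 1460 bp between the sites, had 2 libraries, and the 27 deletion strains, with distances from 24 to 655 bp, had 1 library each. Values of single deletion strains therefore have no replicate error, and comparisons rest on the trend across strains. Libraries held between 3497505 midpoints (99 bp strain) and 23231489 (355 bp strain), with a median of 11211049, which is 0.290 to 1.93 midpoints per bp. Densities below are relative to the genome mean of the same library, and their 95% intervals are exact Poisson intervals that cover counting error only.

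The question of the series was whether the distance between depleted regions goes with nucleosome positioning at HML. The promoter depleted region of the strain without a deletion lay on chromosome 3 from 13447 to 13608, in the coordinates of the deposited data, whose genome build is not given in the sources used here. Its centre, 13528, served as the Rap1 reference point, and the Abf1 point was placed at the labelled distance from it, at 14988 without a deletion. The depleted region nearest to that point ran from 15006 to 15225, and its centre lay 127.5 bp beyond the point. By the order of the gene table, HMLALPHA1, which encodes a mating-type transcription activator, follows the promoter on this side, and CHA1, which encodes a serine deaminase, is the next gene beyond Abf1. The coordinates right of HML were shifted by the labelled loss of DNA, within 1 bp, in 25 of the 27 deletion libraries. The library labelled 238 bp had the coordinates of a 355 bp interval and the library labelled 298 bp those of a 278 bp interval, so positions in the library labelled 238 bp and the library labelled 298 bp are less certain than in the others.

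**Figure D1:**
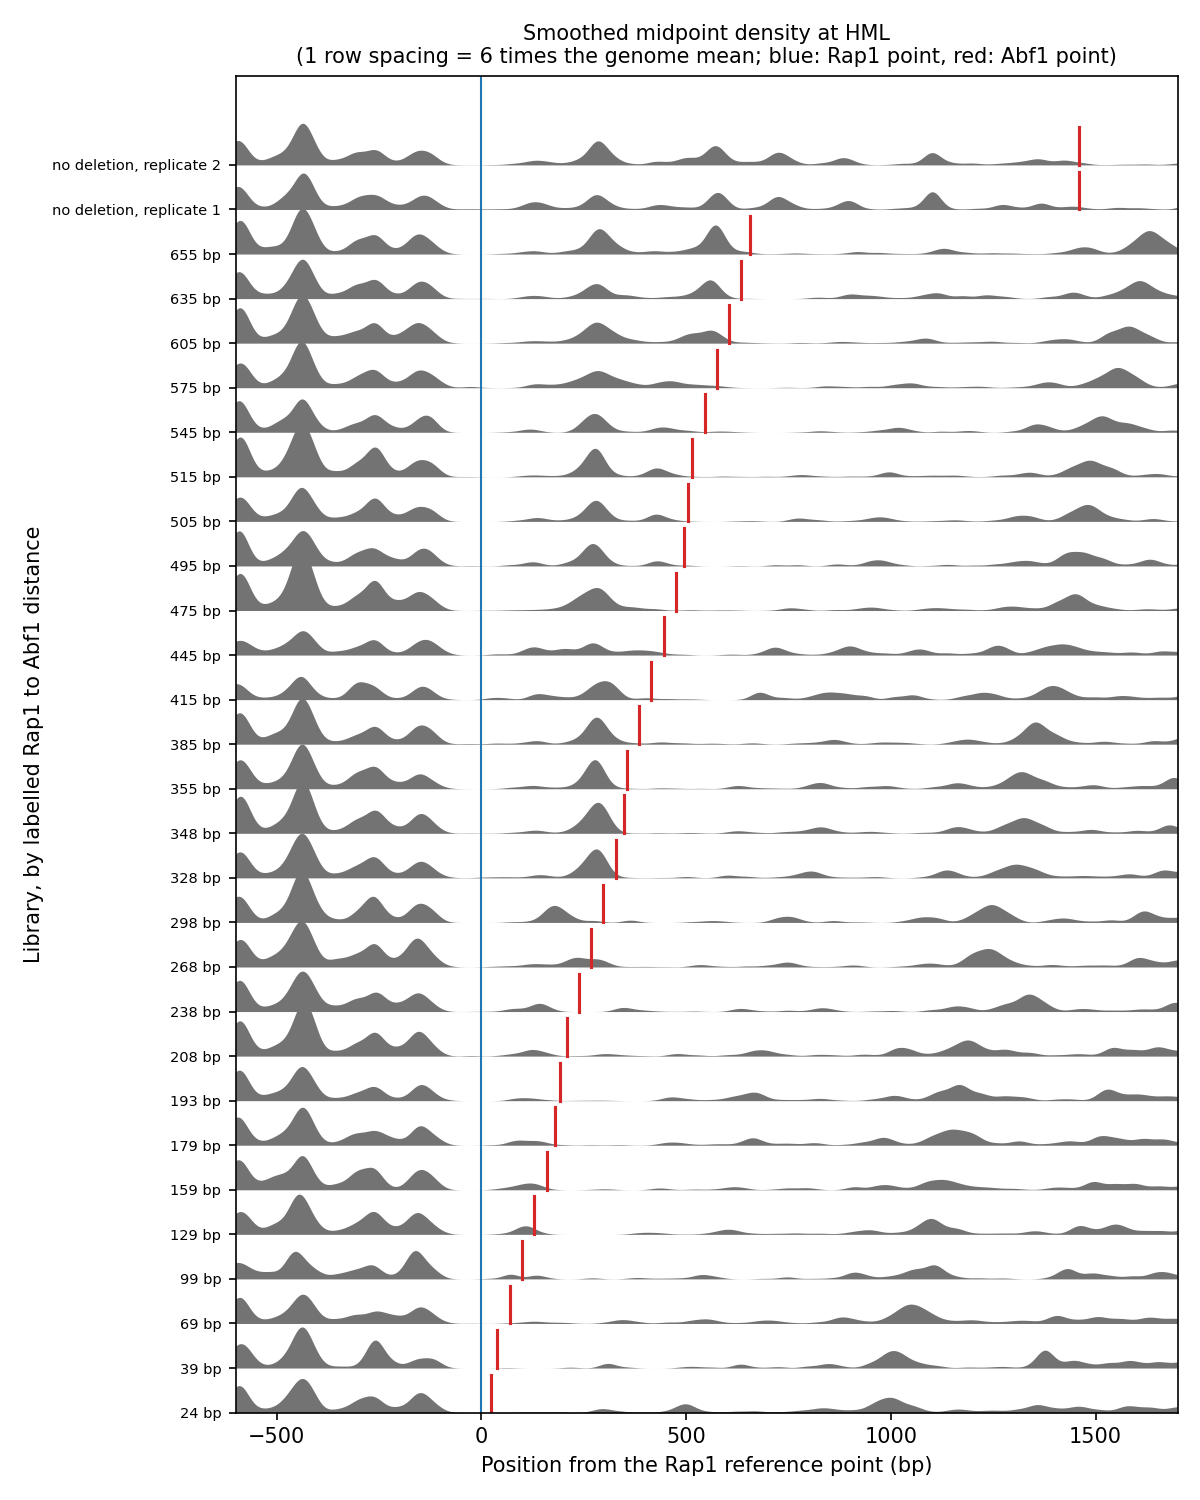
Smoothed midpoint density at HML in 29 libraries, with the position from the Rap1 reference point in bp on the horizontal axis and 1 track per library, ordered by labelled distance, on the vertical axis; a track spacing equals 6 times the genome mean. The blue line marks the Rap1 point and each red line the Abf1 point; strains of 328 bp and more share a peak 272 to 301 bp from Rap1.

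The interval between the sites held almost no nucleosomes in the shortest strains and held more as it grew longer. No midpoint fell between the sites in the 24 bp or the 39 bp strain, and 1 did in the 69 bp strain. These counts allow densities of up to 0.192, 0.266 and 0.0649 of the genome mean. The mean density was 0.348 (95% interval 0.167 to 0.641, from 10 midpoints) at 99 bp, 0.537 at 129 bp and 0.498 at 159 bp. It was 0.183 (0.120 to 0.269) at 193 bp, below the 0.405 (0.330 to 0.492) at 179 bp and the 0.371 (0.283 to 0.479) at 208 bp. It reached 0.635 (0.508 to 0.784) in the library labelled 298 bp and 0.994 (0.905 to 1.09) at 328 bp. The strain without a deletion had 0.665 ± 0.0456 (SD, n = 2) over its longer interval.

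Across the 27 deletion strains, the mean density rose with distance (Spearman rho = 0.710, permutation p = 7e-05, adjusted p = 0.000257; Pearson r = 0.742, permutation p = 2e-05). Without the 2 strains farthest from the median distance, r was 0.656 (permutation p = 0.00035). The sum of midpoints, in units of the midpoints of 160 bp of average genome, rose as well (rho = 0.911, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 5.5e-05; r = 0.938, permutation p = 1e-05, and 0.928 without the 2 farthest). The number of called dyads followed (rho = 0.837, permutation p = 1e-05, adjusted p = 5.5e-05; r = 0.798, permutation p = 1e-05, and 0.750 without the 2 farthest). A longer interval can hold more midpoints and more dyads at a constant density, so the sum and the dyad count carry a trend from length alone. The mean density carries one as well, because the first 80 bp from the Rap1 point belong to the promoter depleted region, which is most of a short interval and little of a long one. The 24, 39 and 69 bp intervals lie wholly within it. In the 24 strains with longer intervals, the whole interval gave rho = 0.587 (permutation p = 0.00292) and the interval counted from the edge of that region 0.289 (permutation p = 0.172; r = 0.320, permutation p = 0.128). In the 22 strains of 150 bp and more, the whole interval gave rho = 0.512 (permutation p = 0.0165) and the interval from the edge 0.362 (permutation p = 0.0996). The sum counted from the edge passed the threshold (rho = 0.884, n = 24, permutation p = 1e-05). From 300 bp upward the whole interval gave rho = -0.386 (n = 15, permutation p = 0.158). Without the depleted edge, a rise of the mean density across these strains thus did not pass the threshold, and a smaller rise is not excluded. The counts from the edge and from 300 bp upward were chosen after the data were seen. Permutation tests of relations with distance were two-sided, and adjusted values are Benjamini-Hochberg values over 11 relations with distance. Among the 14 shallower libraries the mean density gave rho = 0.730 (permutation p = 0.00434) and among the 13 deeper ones 0.560 (permutation p = 0.0499).

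**Figure D2:**
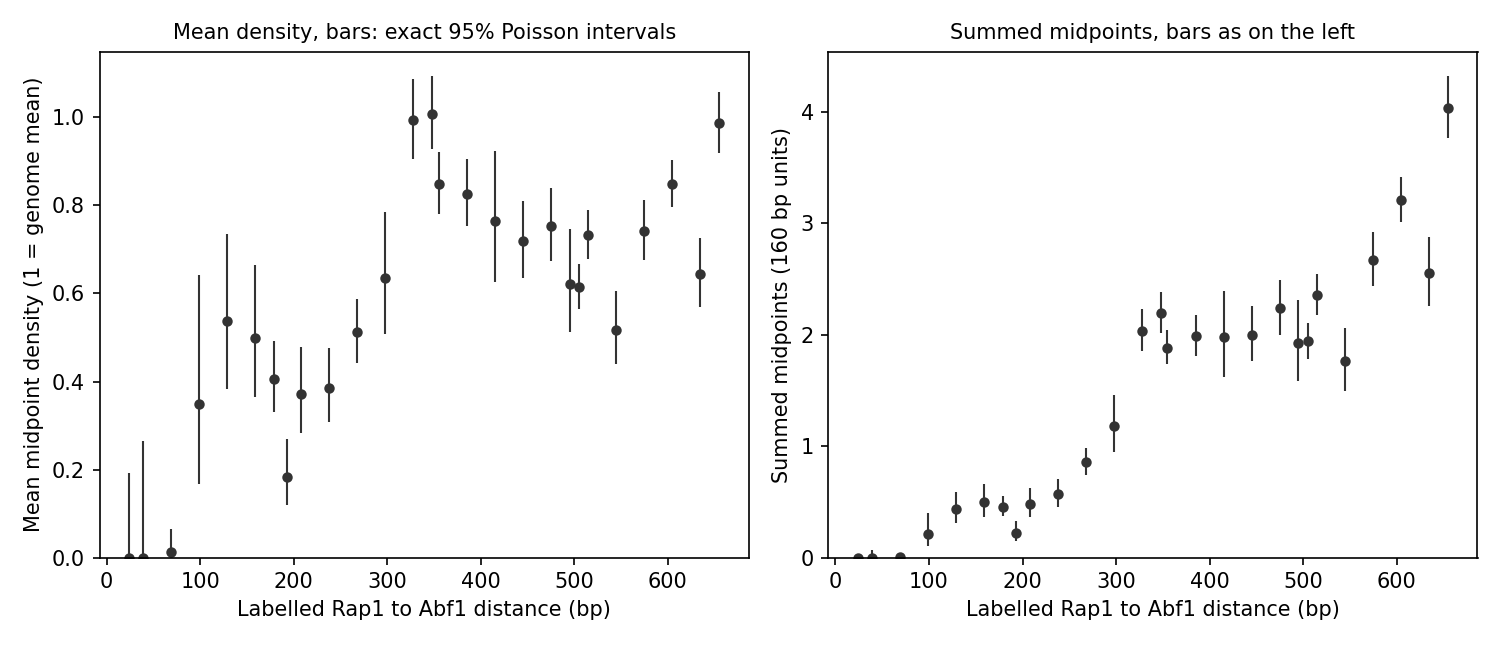
Mean midpoint density between the sites (left, 1 is the genome mean) and summed midpoints (right, in units of 160 bp of average genome) against the labelled distance in bp, 1 point per deletion strain with exact 95% Poisson intervals. The sum lay between 1.76 and 2.67 in the 12 strains of 300 to 600 bp.

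The increase was uneven along the distance. The mean density was 0.179 ± 0.25 (SD, n = 5 strains) under 150 bp and 0.427 ± 0.142 (n = 7) from 150 to 300 bp, a difference of 0.247 that did not pass an exact two-sided permutation test (p = 0.0543 over 792 splits). From 300 to 450 bp it was 0.860 ± 0.118 (n = 6), higher than from 150 to 300 bp (exact permutation p = 0.00117, adjusted p = 0.00466). From 450 to 600 bp it was lower again, at 0.664 ± 0.0944 (n = 6; exact permutation p = 0.0130, adjusted p = 0.0260). From 600 bp upward it was 0.826 ± 0.173 (n = 3; exact permutation p = 0.0952 against the class before). Summed midpoints were 0.609 ± 0.315 from 150 to 300 bp, 2.01 ± 0.102 from 300 to 450 bp, 2.15 ± 0.336 from 450 to 600 bp and 3.27 ± 0.744 above. The step between the classes of 300 to 450 and 450 to 600 bp did not pass the test for the sum (exact permutation p = 0.394), while the steps at 300 bp (exact permutation p = 0.000583, adjusted p = 0.00466), 150 bp (p = 0.0126, adjusted p = 0.0260) and 600 bp (p = 0.0238, adjusted p = 0.0381) did. A sum grows with the length of the interval it covers. The no-deletion average had strong summits (2.61 and 2.43) at 284 and 574 bp from Rap1, shortly before the borders at 300 and 600 bp. A longer window over that profile would also step up there, so these steps need not be an effect of the distance. Below 150 bp, the 24, 39 and 69 bp intervals lie wholly within the promoter depleted region. Counted from the edge of the promoter depleted region, also after the data were seen, the mean density was still higher from 300 to 450 bp (1.06 ± 0.185, n = 6) than from 150 to 300 bp (0.607 ± 0.190, n = 7; exact permutation p = 0.00117, adjusted p = 0.00350 over 3 comparisons) and lower again from 450 to 600 bp (0.780 ± 0.113, n = 6; exact permutation p = 0.0152, adjusted p = 0.0227). The comparisons of neighbouring classes, 8 in all for adjustment, were chosen after the data were seen, except that between under 150 bp and 150 to 300 bp for the mean density. The latter passed the threshold without the 99 bp (p = 0.0485), the 129 bp (p = 0.00606) or the 193 bp strain (p = 0.0368), each by exact permutation.

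Dyads between the sites were called in 23 of the 27 deletion strains. None was called in the 24, 39, 69 and 193 bp strains, 13 strains had 1, 6 had 2 and 4 had 3. In the 99 bp and 129 bp strains the single summit lay 27 and 22 bp from the Abf1 point, with 17 and 44 midpoints within 70 bp of it. A nucleosome wraps about 150 bp, so these intervals cannot hold a whole one, and one centred there would reach past the Abf1 point. Every one of the 15 strains of 328 bp and more had a dyad close to where the strain without a deletion had its own, 282 and 285 bp from Rap1 in the 2 libraries. Its mean position was 281 ± 7.04 bp from Rap1 (SD, n = 15 strains, range 272 to 301), counted among summits within 40 bp of 284 bp. The distance from this dyad to the Abf1 point grew from 48 bp in the 328 bp strain to 64, 78 and 104 bp in the 348, 355 and 385 bp strains. This dyad was the sole called one in these 4 strains, with a summit of 3.90, 4.17, 3.92 and 3.64 times the genome mean. A nucleosome of about 150 bp centred 48 or 64 bp from the Abf1 point would also reach past it. The same holds for the summits 41, 33, 63, 65 and 46 bp from that point in the 159, 268, 445, 495 and 605 bp strains. The Abf1 point is approximate, so whether such nucleosomes cover the site is not settled. In the library labelled 298 bp the dyad lay at 178 bp and in the 268 bp strain at 235 bp from Rap1.

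Some longer intervals held further dyads. A summit 427 to 459 bp from Rap1 was called in 5 of the 10 strains longer than 435 bp, its position in the no-deletion average. These were the strains of 495, 505, 515, 545 and 575 bp, with heights of 0.691 to 1.20. The summit was not called in the 445, 475, 605, 635 and 655 bp strains, where the density there was at most 0.343 to 0.686. In the 445 and 605 bp strains it reached 0.686 and 0.607, above the minimum height of 0.5, without a called summit there. The 2 no-deletion libraries differed in the same way. The first had a called summit of 0.671 at 437 bp, and the second had none, with a highest density of 0.657. Presence or absence of this call in single libraries is therefore uncertain. The 445 and 475 bp intervals end soon after that position and may be too short for a nucleosome there. The 445 bp strain had a summit of 0.703 at 382 bp. At 605, 635 and 655 bp a stronger summit stood at 559, 558 and 571 bp, with heights of 1.76, 2.52 and 3.91. The strain without a deletion had summits at 577 and 571 bp. A weak summit near 133 bp in the strain without a deletion was called in 9 of the 22 strains longer than 133 bp, the shortest of which may lack room for it. The distance from Rap1 to the nearest dyad rose with the interval (rho = 0.599, n = 23, permutation p = 0.00322, adjusted p = 0.00886; r = 0.567, permutation p = 0.00589, and 0.461, p = 0.0377, without the 2 farthest), from 72 bp in the 99 bp strain to 288 bp in the 655 bp strain. A dyad within the interval cannot lie farther from either site than the interval is long, so the relation is partly fixed by construction. From 300 bp upward rho was 0.0519 (n = 15, permutation p = 0.855), and 0.132 (permutation p = 0.634) for the Abf1 side. This relation did not pass the threshold in the 12 deeper libraries (rho = 0.452, permutation p = 0.142) nor with a lower minimum height for a summit (rho = 0.330, permutation p = 0.114). The distance from Abf1 to its nearest dyad ranged from 22 to 194 bp and showed no relation past the threshold (rho = 0.352, permutation p = 0.0981, adjusted p = 0.216; r = 0.371, permutation p = 0.0798, and 0.308 without the 2 farthest), but passed it unadjusted without the 605 bp strain (rho = 0.440, permutation p = 0.0415) and without the 238 and 298 bp libraries (rho = 0.475, permutation p = 0.0311).

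**Figure D3:**
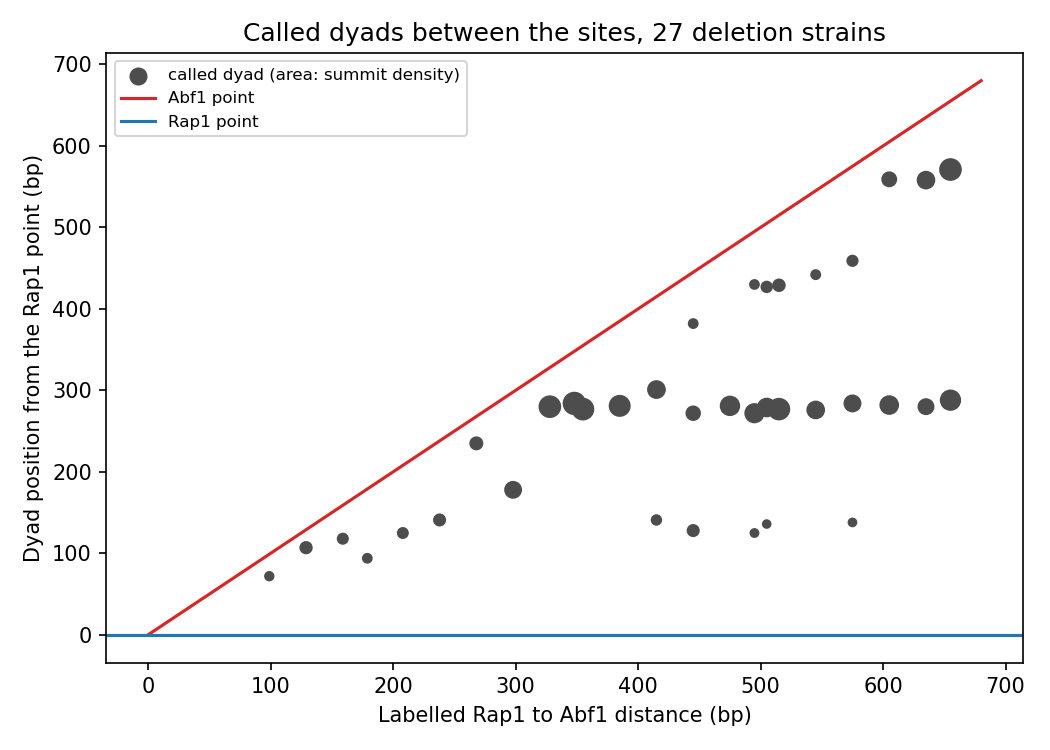
Called dyads in the 27 deletion strains, with the labelled distance in bp on the horizontal axis and the position from the Rap1 point in bp on the vertical axis; point area follows summit density. The Abf1 point moves along the red diagonal, while a row of 15 dyads stays between 272 and 301 bp.

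The flank towards CRE kept its dyads in place. On the flank towards CRE, 7 dyads were found in all 27 deletion strains, at mean distances of 148, 265, 439, 591, 771, 940 and 1084 bp from Rap1, with SDs over strains from 1.64 to 7.16 bp, among summits within 40 bp of a no-deletion dyad. Beyond Abf1, 4 of the 5 dyads matched were found in all 27 strains, at 815, 974, 2030 and 2193 bp from the Abf1 point, and that at 1337 bp in 22 strains. Matching used summits of at least the genome mean in the no-deletion average, so the summit nearest to Abf1, at 479 bp with a height of 0.941, is not among them. The nearest dyad on the CRE flank showed no relation with distance (rho = -0.176, permutation p = 0.377, adjusted p = 0.574; r = -0.169, permutation p = 0.400, and -0.385 without the 2 farthest, permutation p = 0.0588), nor did the nearest dyad beyond Abf1 (rho = 0.143, permutation p = 0.470, adjusted p = 0.574; r = 0.180, permutation p = 0.370, and 0.0474 without the 2 farthest). The latter ran from 110 bp, in the library labelled 238 bp, to 826 bp, with 474 and 482 bp in the 2 no-deletion libraries. Apart from 110, 818 and 826 bp, values lay from 265 to 276 bp or from 442 to 483 bp, so they need not come from 1 dyad that moves. These distances used the Abf1 point from the label, whereas the matched dyads used the point from the coordinates. By its coordinates, the summit at 110 bp in the library labelled 238 bp lies between the sites. Correlations of the 1500 bp profiles with the second no-deletion library ran from 0.802 to 0.981 on the CRE flank and from 0.822 to 0.972 beyond Abf1. With the first they ran from 0.780 to 0.967 and from 0.775 to 0.9405. The 2 no-deletion libraries had 0.935 and 0.905 with each other.

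The Rap1 point lay in depleted DNA in every strain. It was placed at the centre of a depleted region of the no-deletion libraries, so low density there largely follows from its placement. The Abf1 point lies outside its nearest depleted region, so the densities at these points cannot be set against each other. The density within 50 bp of the Rap1 point was 0.0339 ± 0.0360 (SD, n = 27) and at most 0.117, and it did not follow distance (rho = 0.0549, permutation p = 0.784, adjusted p = 0.796; r = 0.112, permutation p = 0.581, and -0.0164 without the 2 farthest). At the Abf1 point it was 0.326 ± 0.375 (n = 27), with no relation past the threshold (rho = 0.150, permutation p = 0.451, adjusted p = 0.574; r = -0.00710, permutation p = 0.973, and -0.135 without the 2 farthest). With both points moved 50 bp to the left, this relation passed the threshold unadjusted (rho = 0.456, permutation p = 0.0178). The density at the Abf1 point reached 1.58 in the 328 bp strain and 1.16 in the 268 bp strain, whose dyads lay 48 and 33 bp from the Abf1 point, inside the measured window.

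How sharply the nucleosomes were positioned was measured as the percent of midpoints within 70 bp of a summit that lay within 20 bp of it. It ranged from 39.6% in the 268 bp strain to 79.5% in the 129 bp strain and showed no relation with distance (rho = 0.0573, n = 23, permutation p = 0.796, adjusted p = 0.796; r = 0.0955, permutation p = 0.662, and -0.000351 without the 2 farthest). A 160 bp period in the distance, fixed beforehand as an approximate repeat of nucleosomes with linkers, accounted for a share of 0.173 of its variance. This did not pass a one-sided permutation test (p = 0.150, n = 23). The repeat measured over genes was longer, 167 to 173 bp. Without the 129 bp or the 179 bp strain the share was 0.287 (permutation p = 0.0420) or 0.282 (permutation p = 0.0447).

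Outside HML, no change with distance was detected. Around 5828 gene starts outside chromosome 3, the depletion before genes relative to the first nucleosome was 0.280 ± 0.0104 (SD, n = 27) and did not pass the threshold against distance (rho = 0.308, permutation p = 0.119, adjusted p = 0.218; r = 0.358, permutation p = 0.0672, and 0.276 without the 2 farthest), although it did so unadjusted without the 69 bp strain (rho = 0.407, permutation p = 0.0399). The nucleosome repeat over genes was 167 to 173 bp in all 29 libraries. Of 12032 windows of 1 kb tested with edgeR's quasi-likelihood test, 0 changed with distance at a Benjamini-Hochberg adjusted p under 0.05; 450 had an unadjusted p under 0.05, against 602 expected by chance, and DESeq2 called 0 with 586 under unadjusted 0.05. In counts simulated with the common dispersion, which do not cover windows of larger spread, 100% of windows with a slope of 0.1 log2 per 100 bp and 72% of those with 0.05 were recovered.

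The windows of each list fixed before the data were examined likewise gave 0 calls, also when adjusted over the list alone: 13 windows of the HML neighbours, among them GEX1 and VBA3, which encode membrane transporters; 56 of silencing factors such as SIR3; 18 of strain markers; 9 of core histone genes; 230 of ribosomal protein genes; 298 of tRNA genes; and 607 near chromosome ends. The 13 windows of the HML neighbours all lie on the CRE side of the Rap1 point, so this list does not cover the side beyond Abf1. Of these 13 windows, 3 had an unadjusted p under 0.05, the smallest being 0.00414 (adjusted p = 0.996) with a slope of -0.129 log2 per 100 bp in the first kb of chromosome 3. The other 2 had slopes of 0.0215. Median slopes of these lists lay between -0.0029 and 0.0021 log2 per 100 bp. Genes of the mating loci were not used in the windows. URA3, a marker of uracil synthesis, had a median density of 0.00163 over its body, at most 0.0519 in any library. LYS2, needed for lysine synthesis, had 0.307 to 0.390 in all libraries. SIR2, SIR3 and SIR4, which encode the silencing complex, had medians of 0.915, 0.819 and 0.980, RAP1 had 1.31 and ABF1 had 1.01.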

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

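Counts without a chromosome, which no comparison used, made up 9.61% of the counts in the 655 bp strain, above both no-deletion libraries (0 and 6.89%). Within classes of the labelled distance, 4 strains stood apart from the others of their class in a test of the gap to the nearest neighbour: the density at the Abf1 point was 1.16 in the 268 bp strain and 1.58 in the 328 bp strain, that at the Rap1 point was 0.0898 in the 575 bp strain, and the nearest dyad beyond Abf1 was 818 bp away in the 475 bp strain. With 33 combinations of class and quantity tested, chance gives about 1 in 20.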

How the results depend on the processing

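Of 187 alternative values for 15 results, 163 kept their direction and side of the threshold. The relations with distance of summed midpoints (rho 0.840 to 0.947) and called dyads (0.770 to 0.892) did so under every alternative run, and the windows stayed at 0 calls under all. The alternative of strains of 300 bp and more was not run for the sum or the dyad count. From 300 to 600 bp alone, the sum did not pass the threshold (rho = 0.0769, n = 12, permutation p = 0.815). Moved reference points, corrected or left-out libraries of doubtful coordinates, partial correlations given the depletion before genes, intervals from the depleted edge, strains of 300 bp and more and most left-out libraries were chosen after the data were seen. The cause of each change in the paragraphs below was not tested. The relation of mean density weakened to 0.289 when counted from the edge of the promoter depleted region, which leaves out 80 bp of depleted DNA and the 3 shortest strains (0.587 for the whole interval in the same 24 strains), and turned to -0.386 from 300 bp upward.

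The relation of the Rap1 side distance weakened to 0.330 with a minimum height of 0.25 to 0.423 with both points 50 bp to the left and to 0.0519 from 300 bp upward. That of the Abf1 side distance passed the threshold without the 2 libraries of doubtful coordinates (0.475), with their distance taken from the coordinates (0.430) and with the Abf1 point at the centre of the depleted region (0.438). The difference between the classes under 150 bp and 150 to 300 bp passed it without the library of fewest midpoints (0.290) and with points 50 bp to the left (0.298), and the 160 bp period did with a minimum height of 1 (0.350). The relation of the density at Abf1 rose to 0.456 with points 50 bp to the left and passed the threshold (permutation p = 0.0178).

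Relations that had not passed the threshold changed sign. The nearest dyad on the CRE flank gave 0.0405 with smoothing of SD 10 bp and 0.178 with summits 120 bp apart. The nearest dyad beyond Abf1 gave -0.328 with SD 30 bp and -0.155 from 150 bp upward. Sharpness gave -0.202 with a minimum height of 1 and -0.00282 without the library of fewest midpoints. The density at Rap1 gave -0.234 from 150 bp upward, -0.299 with points 50 bp to the right and -0.0333 as a partial correlation given the depletion before genes. The density at Abf1 gave -0.0344, -0.137 and, with the centre of the depleted region, -0.250.

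With each library left out in turn, values ran from -0.0381 to 0.123 for the density at Rap1 (below 0 without the 24, 39 or 575 bp strain), from 0.234 to 0.407 for the depletion before genes (highest without the 69 bp strain), from -0.0175 to 0.190 for sharpness (below 0 without the 99, 179 or 268 bp strain), from 0.106 to 0.287 for the period, from 0.203 to 0.337 for the class difference and from 0.260 to 0.440 for the Abf1 side distance. The no-deletion density was 0.632 and 0.697 with each library alone. No paired analysis was possible because each deletion strain had 1 library. Counts were low in the shortest intervals, with 0 to 10 midpoints in the 24, 39, 69 and 99 bp strains, so their values are imprecise. Their upper 95% limits of 0.192, 0.266, 0.0649 and 0.641 still lay below the genome mean, by counting error only. The 24, 39 and 69 bp intervals lie wholly within the depleted region used to place the Rap1 point, so low density there largely follows from that placement. PCR copies would widen the limit at 99 bp, which rests on 10 midpoints, so it does not settle what depth contributes there.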

Other observations

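All tests in this part were chosen after the data were seen. From 300 to 600 bp the summed midpoints showed no relation past the threshold with distance (rho = 0.0769, n = 12 strains, permutation p = 0.815; r = 0.326, permutation p = 0.310, and -0.0629 without the 2 farthest) and averaged 2.08 ± 0.247 units (SD, n = 12). The mean density is this sum divided by the distance, so its fall in the same strains is largely the same observation, not a separate one (rho = -0.825, permutation p = 0.00166; r = -0.825, permutation p = 0.00076, and -0.894 without the 2 farthest; rho from -0.918 to -0.773 with each strain left out), opposite in sign to the relation over all 27. It fell when counted from the edge of the promoter depleted region as well (rho = -0.825, permutation p = 0.00159). The no-deletion average had summits of 2.61 at 284 bp, 0.585 at 435 bp and 2.43 at 574 bp from Rap1. A longer window over that profile would also add little between the stronger summits, so a flat sum need not be an effect of the distance. Growth of the sum that differences in depth or digestion had hidden would appear once these are held constant. The partial rank correlation given total midpoints was 0.173 (permutation p = 0.585) for the sum and -0.818 (permutation p = 0.00161) for the mean density. Given the depletion before genes, the values were 0.0919 (permutation p = 0.771) and -0.832 (permutation p = 0.00115). No growth of the sum past the threshold appeared, but 12 strains cannot exclude it. The mean density falls with distance wherever the sum is flat, so its values do not decide. Depth and digestion therefore stay open.

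The dyad near 281 bp held its distance from Rap1 while its distance from Abf1 grew to 367 bp. If it were placed by its distance from Abf1, profiles should match best when aligned there. The dyad is a main peak of these profiles, so aligning them largely restates its position and adds no separate evidence. The profiles of the 15 strains of 300 bp and more had a median mean correlation with the others of 0.119 when aligned at Abf1 and of 0.904 when aligned at Rap1, where all 15 correlated better; without the 100 bp next to the aligned point the medians were 0.105 and 0.896, again with all 15 higher at Rap1. This comparison was chosen after a test on the highest point between the sites had given no clear answer over all 15 strains, with a slope of 0.576 bp per bp (95% interval 0.123 to 1.03), since it lay at 558 and 571 bp in the 635 and 655 bp strains; from 300 to 600 bp the slope was -0.0181 (-0.0820 to 0.0459, n = 12). Placement by the DNA sequence beneath the dyad may give the same pattern and stays open, because which part of the sequence each deletion removed was not analysed here.

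The library labelled 238 bp had coordinates of a 355 bp interval, 117 bp more than its label. Its longest stretch without a midpoint between the sites was 159 bp, beyond the 94 bp of any other library. This is consistent with reads of a shorter interval aligned to a longer genome, which predicts a stretch of at least the excess, but the hypothesis came from the same values. The positions within 40 bp of the dyad near 284 bp, where the 355 bp strain had 453 midpoints, lie inside this stretch, so the same midpoints bear on a true 355 bp interval. That explanation predicts the dyad called there in all 15 strains of 300 bp and more; the highest smoothed density was 0.326, against 1.65 to 4.17 in those strains, which argues against it. No biological explanation was tested. For the library labelled 298 bp, whose coordinates fell 20 bp short of the label, no test was made.

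Among 60 random orders of the distances, 57 called 0 windows, as did the real order; the other 3 called 1, 638 and 676.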
